A study of Homo sapiens with 6 samples.

How the data were processed

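The study measured contacts of the FGF18 viewpoint by 4C-seq in 6 libraries of K562 cells. Per the labels' protocols, chromatin was cut with HindIII and then DpnII, and libraries were sequenced on a MiSeq. Per the submitters' processing notes, Bowtie2 2.2.5 and the genome build hg19 were used. The program that called interactions, its filters and its treatment of the viewpoint fragment are not given in the sources used here. Each deposited file lists the HindIII fragments that had at least 1 read in 1 library, with 4 measurements. The read counts per fragment are raw counts as deposited by the authors, per the file headers. A column the authors headed RPMs is treated here as a score, because its values sum to 1279311 to 1766322 per library and are a power of the read count with an exponent between 0.811 and 1.57 set per library; it was used for no test. The p-value and q-value per fragment are those the authors deposited for each library.

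Groups and replicate numbers came from the sample titles: EV, S1KO and DKO, with 2 libraries each. Fragments not listed for a library were counted as 0. The viewpoint fragment was taken as the chr5 fragment with most reads over all libraries, chr5:170851908-170853009, which lies beside an unlisted interval, chr5:170840932-170851907, the probable bait fragment. The 3 fragments within 10 kb, itself included, were left out of the tests. None of them lies below the viewpoint fragment, because the 10 kb below it fall within the unlisted interval. Fragments just below the probable bait were therefore kept. Replicates were compared first: over chr5 fragments the Spearman correlation between replicates was -0.014 in EV, 0.059 in S1KO and 0.086 in DKO, and over 50-kb windows within 2 Mb it was 0.84, 0.88 and 0.95. These are correlations across regions, which are not independent replicates. Of 20398 chr5 fragments with a read in any library, 366 had reads in all 6. Fragments of other chromosomes held a median of 10 to 34 reads per library over those the library lists, leaving out those counted as 0. Deviations of replicate 1 in 1 group did not follow those in another (correlations of -0.283 to 0.0644 over the windows within 2 Mb), so the replicate numbers were not used as pairs.

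Before the data were examined, the tests over all of chr5, the counts of called interactions, the shares of reads, the overlap of calls, the search for deleted fragments and the rule for named regions were fixed. CPM values are reads scaled to the chr5 reads outside the 10-kb zone. They leave out the TMM factors that the log2 fold changes over chr5 include, so the ratio of 2 CPM means can differ from the fold change. Counts per fragment, and sums over 50-kb windows counted from the viewpoint midpoint, were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, all 6 libraries in 1 fit, at least 10 reads in at least 2 libraries, chr5 reads outside the 10-kb zone as library size, TMM). Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. DESeq2 1.42.0 served as an alternative. For each comparison the rule names, among regions past the threshold with both libraries of 1 group above both of the other, the 10 with the largest absolute log2 fold change within 2 Mb and the 5 largest elsewhere. Where fewer than 5 pass, it names all of them and those with the lowest p up to 5, given as values that did not pass. It also names the 10 fragments with most EV reads.

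Chosen after seeing the data were the test of 80 windows of 50 kb within 2 Mb (library size: reads within 2 Mb, no further scaling), the ratio of reads above to below the viewpoint, and the test of other chromosomes. For the last, the numbers of fragments with at least 1 read were tested with edgeR in 281 windows of 10 Mb with more than 60 such fragments over the 6 libraries. Shares and ratios were compared by exact permutation tests with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 drew the plots. With 2 libraries against 2, an exact two-sided test cannot go below 0.333. The alternatives were other scalings, filters, window sizes and viewpoint zones, DESeq2, capped reads, the replicate number as a block, the 4 libraries compared alone, other q thresholds and leaving out each library in turn.

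The procedures were tested on simulated data made from the mean counts and library sizes of these libraries, for DKO against EV. Over chr5, every feature was given the same dispersion, the common value of the real fit (5.06 for fragments, 2.68 for windows). With it, 0% of 100 fragments and 0% of 100 windows changed 16-fold were recovered (2803 fragments and 2705 windows tested). The real fit did call windows, at log2 2.08 and 2.05, so this simulation does not describe the windows with many reads. With the dispersion set to 0.1 instead, 62% of the fragments and 92% of the windows changed 16-fold were recovered. For the windows within 2 Mb, 10% of 10 windows changed 2-fold and 80% of 10 changed 4-fold were recovered, with 0 false calls among 80. Here too every window had the same dispersion, 0.126. The real fit called windows with many reads at log2 1.05 and 1.01, so the 10% need not hold for those. For other chromosomes, 90% of 20 windows changed 1.5-fold were recovered among 281.

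The 3 gene lists planned for testing (neighbours of FGF18, developmental genes and housekeeping genes of chr5) were not analysed here, because gene positions on hg19 were not used here and the gene table at hand is of another build, GRCh38.p14. That table gave only the order of genes around FGF18.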

Results

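The data are 6 chromosome conformation capture (4C-seq) libraries from K562, a human chronic myeloid leukaemia cell line. In 4C-seq, crosslinked chromatin is cut and religated, and every fragment ligated to 1 chosen fragment, the viewpoint, is amplified and sequenced. The viewpoint lies at FGF18, which encodes the secreted fibroblast growth factor 18. There were 3 groups with 2 libraries each: empty-vector control cells (EV), cells from which silencer 1 was excised (S1KO), and cells from which silencers 1 and 2 were excised (DKO). The question the design puts is whether removing these silencer elements changes which parts of the genome touch FGF18. The libraries held 708503 and 1919737 reads (EV), 1270579 and 1238383 reads (S1KO), and 1765929 and 1300415 reads (DKO). Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

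In EV cells the strongest contacts of FGF18 lay on both sides of the viewpoint fragment, chr5:170851908-170853009 (hg19). In the order of genes given by the GRCh38.p14 annotation, NPM1 (nucleophosmin) and TLX3 (a homeobox transcription factor) are the nearest protein-coding neighbours on the centromeric side. SMIM23, FBXW11 (an F-box protein of a ubiquitin ligase) and STK10 (a protein kinase) are the nearest on the telomeric side. No gene positions on hg19 were used here, so regions are given by coordinates and by their distance from the viewpoint, with "below" for the centromeric and "above" for the telomeric side. Outside the 10 kb beside the viewpoint, the fragment with most reads in EV was chr5:170835262-170840025, at 30486 ± 7426 CPM (reads scaled to the chr5 reads outside those 10 kb; SD, n = 2). It was followed by chr5:170820839-170833077 at 12930 ± 1566 and chr5:170862833-170866306 at 11560 ± 6853. The strongest, chr5:170835262-170840025, lies just below the unlisted interval chr5:170840932-170851907, the probable bait fragment. It is thus not 10 kb away from the probable bait. The other 7 of the 10 strongest EV fragments held 4728 to 6844 CPM, and 1 of them, chr5:171055025-171064475, lay 207 kb above the viewpoint while the rest lay within 62.1 kb of it. None of these 10 fragments passed edgeR's quasi-likelihood test in any comparison.

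**Figure D1:**
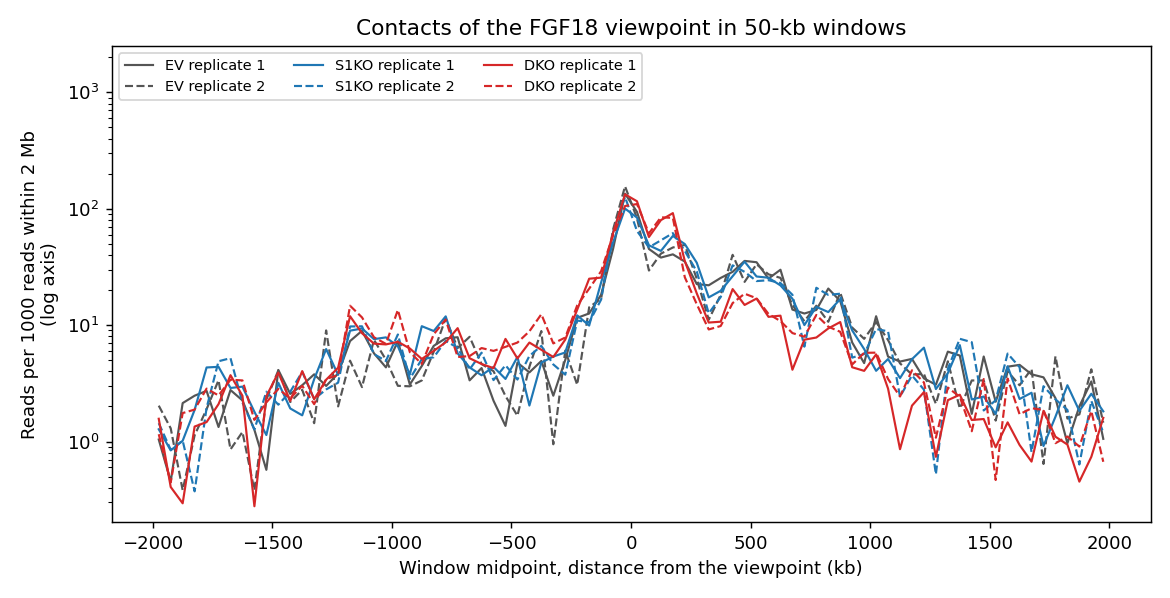
Reads in each 50-kb window (y axis, reads per 1000 reads within 2 Mb of the viewpoint, log axis) against the window's distance from the viewpoint (x axis, kb) for the 6 libraries, with 1 line per library. From 100 to 200 kb above the viewpoint both DKO lines lie above the others, and from 250 kb above onward they mostly lie below them.

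Excision of silencer 1 alone left the contact profile within 2 Mb of FGF18 without a window past the threshold. The 2 largest changes among the windows with the lowest p lay below the viewpoint, in windows with few reads. The window chr5:170502458-170552457, 350 kb below, held 4.98 ± 0.55 reads per 1000 in S1KO and 1.71 ± 1.08 in EV (SD, n = 2 each; log2 fold change 1.54, SE 0.56, edgeR adjusted p = 0.58). With 1 library left out its log2 fold change lay between 1.01 and 2.39. The window chr5:170302458-170352457, 550 kb below, held 3.98 ± 0.76 in S1KO and 1.91 ± 0.78 in EV. Above the viewpoint, chr5:171002458-171052457 held 59.99 ± 2.37 in S1KO and 43.5 ± 4.16 in EV (log2 0.46, SE 0.20, edgeR adjusted p = 0.58). With capped reads this window stood at log2 -0.00867, and by numbers of fragments with at least 1 read at -0.26. Of the 80 windows, 0 passed edgeR's adjusted p of 0.05, 3 had an unadjusted p under 0.05, and DESeq2 called 0 with 8 under 0.05. Without EV replicate 1, edgeR called 3 windows, all of them higher in S1KO.

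Across all of chr5, single fragments and 50-kb windows gave 0 calls for S1KO against EV, with 47 of 5017 fragments and 72 of 3091 windows at an unadjusted p under 0.05. DESeq2 called 21 fragments and 25 windows. The fragment with the lowest p was chr5:170970838-170983335, 125 kb above the viewpoint, at 7524 ± 568 CPM in S1KO and 3007 ± 988 in EV (log2 1.30, SE 0.30, edgeR adjusted p = 0.44). Nearby, chr5:171021955-171042009 stood at 5394 ± 1412 and 1797 ± 86.9, and chr5:171010438-171016070 at 4472 ± 1822 and 1922 ± 43.3. The fragment chr5:169204985-169210843 had 0 reads in both EV libraries and 228 and 69 in the S1KO libraries, at least 32.4-fold higher against a floor of 3 reads per library, with the same edgeR adjusted p of 0.44. Among the windows, chr5:149502458-149552457 (at -21350 kb) had the lowest p, at 757 ± 46.8 in S1KO and 10.1 ± 14.2 in EV (edgeR adjusted p = 1). Of 20398 chr5 fragments 366 had reads in all 6 libraries. In simulated data with the same dispersion for every feature, 16-fold changes in DKO against EV were recovered in 0% of fragments and 0% of windows. That does not describe windows with many reads, since the real fit called such windows for DKO against EV at log2 2.08 and 2.05.

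In cells lacking both silencers, the distribution of contacts of FGF18 within 2 Mb differed from that in EV. The stretch from 100 to 200 kb above the viewpoint, chr5:170952458-171052457, took 83.0 ± 6.33 of every 1000 reads within 2 Mb in EV, 108 ± 9.53 in S1KO and 169 ± 2.59 in DKO (SD, n = 2 each), 2.04 times the EV level in DKO. The stretch from 250 kb to 2 Mb above the viewpoint, chr5:171102458-172852457, took 379 ± 19.6 in EV, 357 ± 0.153 in S1KO and 204 ± 9.87 in DKO, 0.539 times the EV level. From 100 kb to 2 Mb below, the level was 170.1 ± 7.40 in EV, 196.0 ± 16.3 in S1KO and 244 ± 22.2 in DKO. Among the 80 windows, 14 passed edgeR's adjusted p of 0.05 for DKO against EV, 6 higher and 8 lower. This set of windows within 2 Mb, scaled to the reads within 2 Mb, was chosen after the data had been seen.

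The windows that rose in DKO included chr5:170952458-171002457, from 39.6 ± 2.17 to 82.0 ± 3.23 reads per 1000 (log2 1.05, SE 0.21, edgeR adjusted p = 0.00016). The window next to it, chr5:171002458-171052457, rose from 43.5 ± 4.16 to 87.5 ± 5.81 (log2 1.01, SE 0.20, edgeR adjusted p = 0.00016). Below the viewpoint, 3 sparse windows rose: chr5:170302458-170352457 (log2 1.88, edgeR adjusted p = 0.0094), chr5:170502458-170552457 (log2 1.84, edgeR adjusted p = 0.013) and chr5:169652458-169702457 (log2 1.12, edgeR adjusted p = 0.018). With 1 library left out they lay, in this order, at log2 1.52 to 2.37, 1.31 to 2.70 and 0.87 to 1.43. Among the windows past the threshold, the largest fall lay 600 kb above the viewpoint at chr5:171452458-171502457, from 27.7 ± 3.13 to 11.4 ± 0.87 (log2 -1.27, SE 0.28, edgeR adjusted p = 0.00044). Falls also passed at chr5:171502458-171552457 (log2 -1.17), chr5:171402458-171452457 (log2 -1.11), chr5:171202458-171252457 (log2 -1.09) and chr5:171352458-171402457 (log2 -1.004), with edgeR adjusted p-values of 0.0022 to 0.0089. From 250 kb to 1 Mb above the viewpoint 15 of 15 windows were lower in DKO than in EV, 8 of them past the threshold. From 1 to 2 Mb above, 20 of 20 were lower and 0 passed, 7 of them with an unadjusted p under 0.05.

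**Figure D2:**
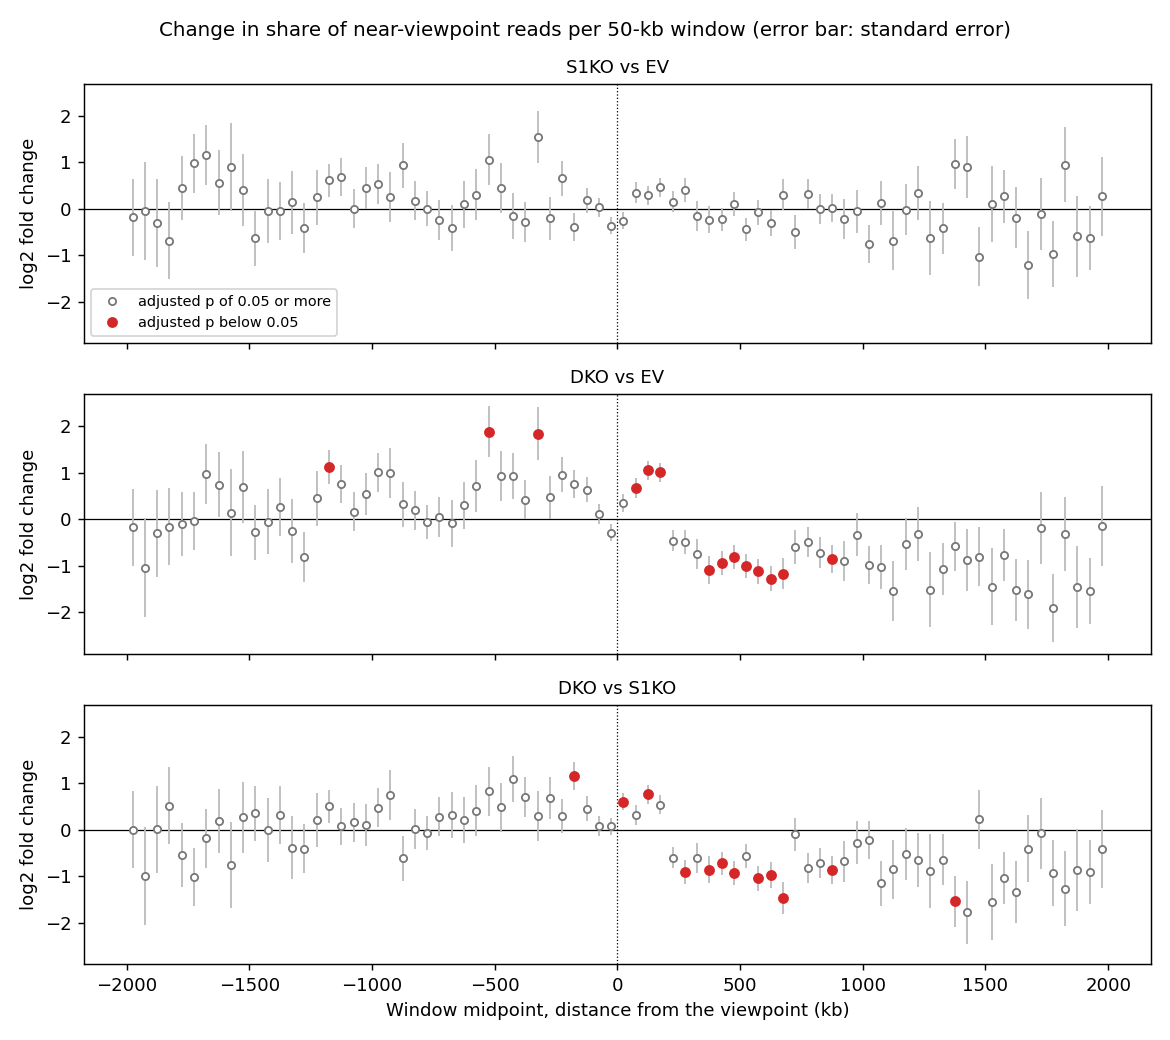
The log2 fold change of each 50-kb window (y axis; error bars, standard error from edgeR) against its distance from the viewpoint (x axis, kb) for the 3 comparisons, with filled points at an adjusted p below 0.05. In both DKO panels the filled points from 250 kb above the viewpoint on lie below 0 and the other filled points above 0, and the panel of S1KO against EV has none.

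The directions are relative to the scaling. For DKO against EV the median window stood at log2 -0.21, with TMM at -0.10, with DESeq2 size factors at 0.00, with reads within 10 Mb at -0.10 and with chr5 totals at 0.30. The calls were then 6 higher and 5 lower with TMM, 10 and 5 with DESeq2 size factors, 10 and 7 with reads within 10 Mb, and 12 and 0 with chr5 totals. Each of the 10 named windows kept its direction under these 4 scalings. They had been named for the largest changes, and a scaling moves all windows nearly alike, so this says little. Smaller falls above the viewpoint, such as log2 -0.49 from 250 kb and -0.33 from 950 kb, lie within reach of such a shift. Without DKO replicate 1 the 14 calls fell to 4, without DKO replicate 2 to 5, and 25-kb windows gave 5. Each of the 4 EV and DKO libraries was left out in turn. The windows starting 100, 150 and 600 kb above the viewpoint then lay at log2 0.997 to 1.11, 0.914 to 1.11 and -1.39 to -1.15. The 3 named windows below the viewpoint moved more, the one starting at -350 kb from 1.31 to 2.70. Counts of fragments with at least 1 read per window gave 0 calls, and the 2 windows 100 to 200 kb above the viewpoint then stood at log2 -0.20 and -0.38. With reads capped at the 90th percentile per fragment neither of these 2 windows passed, and the one from 150 kb stood at log2 -0.10.

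The test over all of chr5 called the same stretch for DKO against EV. Of 3091 windows edgeR called 2, both higher in DKO, while DESeq2 called 87, 28 higher and 59 lower. The edgeR calls were chr5:170952458-171002457 at 46691 ± 3115 CPM against 15253 ± 3073 in EV (log2 2.08, SE 0.44, edgeR adjusted p = 0.039), and chr5:171002458-171052457 at 49716 ± 1945 against 16672 ± 2688 (log2 2.05, SE 0.43, edgeR adjusted p = 0.039). The log2 fold changes include TMM and the CPM values do not, so the CPM means differ by less than the fold changes. The lowest p among the other windows within 2 Mb was that of chr5:170302458-170352457, at 4008 ± 334 and 703 ± 112 (edgeR adjusted p = 0.26). Among the fragments, 0 of 5017 passed, 83 had an unadjusted p under 0.05, and DESeq2 called 28. The lowest p belonged to chr5:170970838-170983335 with 9813 ± 873 CPM in DKO and 3007 ± 988 in EV (log2 with TMM 2.10, SE 0.31, edgeR adjusted p = 0.098), followed by chr5:171010438-171016070 with 8262 ± 1757 and 1922 ± 43.3 (log2 with TMM 2.48, SE 0.37, edgeR adjusted p = 0.098). The 2 window calls were lost without EV replicate 2, without either DKO replicate, with 200-kb windows, with capped reads and with only the 4 libraries compared, while 14 windows passed without EV replicate 1. Without TMM the calls were 4 higher and 1 lower.

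The ratio of reads above to reads below the viewpoint does not depend on scaling, and it fell in DKO at every distance beyond 250 kb. From 250 to 500 kb EV libraries held 5.87 ± 0.693 reads above for each read below, S1KO 5.37 ± 0.453 and DKO 2.00 ± 0.586 (SD, n = 2 each). The DKO minus EV difference was -1.58 on the log2 scale there, -1.35 from 500 kb to 1 Mb, -1.31 from 1 to 2 Mb, -0.90 from 2 to 5 Mb and -0.86 from 5 Mb to the last fragment listed on chr5, which ends at 180781346. In each of these 5 bands both DKO libraries lay below all 4 others, with an exact permutation p of 0.0667, the smallest that 2 against 4 libraries can give. Against the EV libraries alone the two-sided exact permutation p was 0.333 in each band, the smallest for 2 against 2. From 10 to 250 kb the order was the opposite, with ratios of 1.05 ± 0.118 in EV, 1.31 ± 0.181 in S1KO and 1.53 ± 0.0888 in DKO. Counted by fragments with at least 1 read, that order was not kept, with 0.845 and 1.18 in the EV libraries, 0.820 and 0.845 in S1KO and 0.817 and 0.806 in DKO. In this band the sides start at unlike distances from the probable bait, since no fragment just below it was left out. Of the reads below, chr5:170835262-170840025, beside the probable bait, held 5326 of 15170 and 5190 of 16765 in EV. In S1KO it held 6299 of 25784 and 5923 of 24319, and in DKO 19039 of 62405 and 15344 of 62236. The ratios from 10 to 250 kb depend on this fragment. For S1KO against EV the differences in the 5 bands were, outward, -0.13, -0.32, -0.43, 0.29 and 0.21, and -0.31 (SE 0.084) over 250 kb to 2 Mb, where both S1KO libraries lay below both EV libraries (exact permutation p = 0.333). From 250 kb to 11 Mb in all, DKO minus EV was -1.04 by reads and -0.58 by the number of fragments with at least 1 read. This ratio was also chosen after the data had been seen.

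**Figure D3:**
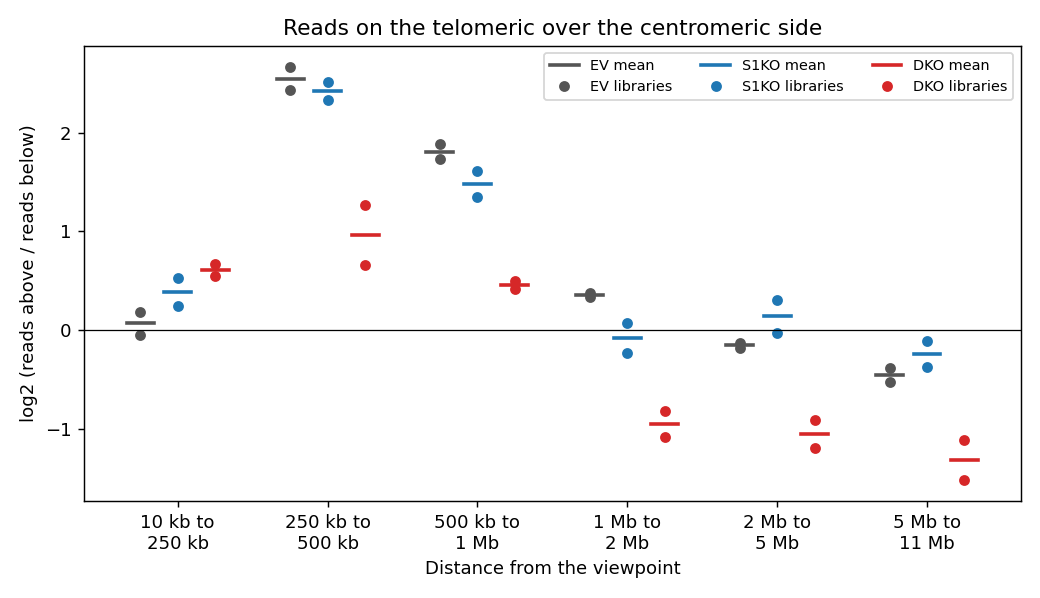
The log2 ratio of reads above to reads below the viewpoint (y axis) in 6 distance bands (x axis) for each library (points) with the group mean (bars, n = 2). Both DKO points lie below the other 4 from 250 kb on, and above the EV points from 10 to 250 kb.

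The comparison of DKO with S1KO asks what the removal of silencer 2 adds to that of silencer 1. It cannot tell silencer 2 apart from the clone or pool that carries the excision. In DKO against S1KO, 12 of the 80 near windows passed, 3 higher and 9 lower, and 8 of them had also passed against EV, in comparisons that share the DKO libraries. The window chr5:171502458-171552457 stood at 17.5 ± 0.96 reads per 1000 in S1KO and 6.34 ± 3.12 in DKO (log2 -1.47, SE 0.34, edgeR adjusted p = 0.0037). The DKO libraries held 4.14 and 8.54 there. With 1 library left out the log2 fold change lay between -2.08 and -1.04, and against EV between -1.78 and -0.74. Falls also included chr5:172202458-172252457, 1350 kb above, from 7.18 ± 0.634 to 2.47 ± 0.072 (log2 -1.54, edgeR adjusted p = 0.041), and chr5:171102458-171152457, from 31.6 ± 3.83 to 16.9 ± 2.56 (log2 -0.90, edgeR adjusted p = 0.010). The windows chr5:170652458-170702457, 200 kb below (log2 1.15, edgeR adjusted p = 0.0079), and chr5:170952458-171002457 (log2 0.76, edgeR adjusted p = 0.0087) rose, but by numbers of fragments with at least 1 read they stood at log2 -0.0742 and -0.12. The median window stood at log2 -0.20, and at 0.10 with chr5 totals. Calls were 1 higher and 1 lower with TMM, 4 and 1 with DESeq2 size factors, 4 and 0 with chr5 totals and 4 and 5 with reads within 10 Mb. There were 0 edgeR calls with 25-kb windows (24 at an unadjusted p under 0.05), without S1KO replicate 1 (19) and without DKO replicate 1 (15), against 20 by DESeq2 with all libraries, and 1 without DKO replicate 2 and 7 without S1KO replicate 2.

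Over all of chr5, DKO against S1KO gave 0 calls among fragments (46 at an unadjusted p under 0.05, 22 by DESeq2) and 0 among windows (81 under 0.05, 54 by DESeq2). Without DKO replicate 2, 1 fragment passed. The lowest p among fragments was that of chr5:170835262-170840025, 14.8 kb below the viewpoint, at 38396 ± 8011 CPM in DKO and 23998 ± 1336 in S1KO (log2 1.09, SE 0.17, edgeR adjusted p = 0.32). This fragment lies just below the unlisted interval taken as the probable bait. The log2 fold change includes TMM and the CPM values do not. Next came chr5:170960981-170962712, 109 kb above, at 6231 ± 2856 and 1350 ± 300 (edgeR adjusted p = 0.52).

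DKO libraries also held more of their reads on chr5 and close to FGF18. Such shares also reflect the quality of a 4C library, so quality and contacts cannot be told apart in them. Outside the 10 kb beside the viewpoint, chr5 took 16.0% ± 7.41 of reads in EV, 20.5% ± 1.70 in S1KO and 31.0% ± 8.17 in DKO (SD, n = 2 each). Within 1 Mb of the viewpoint lay 33.5% ± 8.16 of the chr5 reads in EV, 40.0% ± 1.73 in S1KO and 50.4% ± 0.542 in DKO. DKO exceeded EV in both shares, by 16.9 percentage points for the second, with an exact two-sided permutation p of 0.333 for each, the smallest possible. Counted by fragments with at least 1 read, the differences were 5.32 points on chr5 and 0.215 within 1 Mb. EV replicate 2 held the lowest share on chr5, 11.6% of all reads (95% Wilson interval 11.5% to 11.6%) against 22.2% in EV replicate 1, and without it the S1KO minus EV difference was -0.790 in place of 4.45 points (without EV replicate 1, 9.69). The DKO minus EV difference in the share on chr5 was 9.76 points without EV replicate 2 and 9.22 without DKO replicate 2, and in the share within 1 Mb 11.2 without EV replicate 2. For S1KO minus EV the share within 1 Mb differed by 6.51 points with all libraries (exact permutation p = 0.667), by 0.732 without EV replicate 2 and by 12.3 without EV replicate 1. The Wilson intervals cover counting error only, since reads without molecular identifiers are not independent molecules. By distance, the share of chr5 reads 100 to 500 kb below the viewpoint was 2.35% ± 0.794 in EV and 5.78% ± 0.645 in DKO. From 500 kb to 2 Mb below, the share was 4.29% ± 1.18 in EV and 8.14% ± 1.00 in DKO. At the same distance above, it was 9.85% ± 2.81 in EV and 7.54% ± 1.05 in DKO. There EV replicate 2 (7.86%) lay under DKO replicate 2 (8.28%), so by share of chr5 reads the groups overlapped. The share 2 to 10 Mb above the viewpoint was 4.34% ± 0.756 in EV, 5.25% ± 0.294 in S1KO and 2.65% ± 0.534 in DKO.

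The interactions called by the authors (deposited q below 0.05) lay around FGF18 on chr5 and scattered over other chromosomes, the latter mostly in EV and S1KO. On chr5, 32 fragments were called in at least 1 library, all between 68.2 kb below and 595 kb above the viewpoint, and 6 were called in all 6. The calls include fragments within the 10 kb left out of the tests: the viewpoint fragment itself and chr5:170858283-170862828, both called in all libraries, and chr5:170853014-170858278. In both replicates, 7 fragments were called in EV, 14 in S1KO and 10 in DKO. Of the 7 in EV, S1KO kept 7 and DKO kept 6, and the other one, chr5:170784301-170796497, was called in 1 DKO library. None was called in neither library of a knockout. A fragment counts as gained if called in both libraries of a knockout and in neither EV library. One called in both knockout libraries and in 1 EV library counts as neither kept nor gained. S1KO gained 4 fragments: chr5:170804582-170813634, chr5:170970838-170983335, chr5:171021955-171042009 and chr5:171055025-171064475. DKO gained 1, chr5:170970838-170983335, which held 344 and 762 reads in EV and 4507 and 4311 in DKO. The mean Jaccard index over all calls was 0.214 within the 3 groups and 0.123 between groups, with a one-sided exact permutation p of 0.0667, the smallest that 15 pairings allow. The DKO pair had 0.435, the S1KO pair 0.165 and the EV pair 0.0432, below the lowest value between groups, 0.0449. On chr5 alone the means were 0.528 and 0.462, and 2 of the 15 pairings gave as large a difference (exact permutation p = 0.133). With 1 library of a group left out, its calls rest on a single library: S1KO and DKO then each lost 99 without EV replicate 1 and 51 without EV replicate 2. S1KO then gained 7 without EV replicate 1, 47 without S1KO replicate 1 and 30 without S1KO replicate 2, and DKO gained 4 without EV replicate 1, 9 without DKO replicate 1 and 3 without DKO replicate 2 (where it lost 1). On other chromosomes 212 fragments were called, 49 and 99 in the EV libraries, 22 and 40 in S1KO and 2 and 0 in DKO, and 0 of them in more than 1 library.

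The labels give no position for the silencers, so the excisions could not be looked up directly. No fragment within 2 Mb had at least 50 reads in each EV library and none in both libraries of a knockout, among 168 fragments with that many EV reads. This rule could find only an excision that removed a whole HindIII fragment on every copy, so its outcome does not tell where the silencers lie. By the same rule 1 of 280 fragments had reads in S1KO and none in DKO. In the other direction, 7 of 280 had reads in S1KO and 21 of 428 in DKO with none in EV, and 7 of 428 had reads in DKO and none in S1KO. The fragment chr5:170853014-170858278, beside the viewpoint and chosen after its values were seen, held 15.2 ± 3.77 reads per 1000 in EV, 8.62 ± 5.76 in S1KO and 1.04 ± 0.892 in DKO (SD, n = 2 each; here per 1000 reads within 2 Mb with the 10 kb beside the viewpoint included). Its neighbour chr5:170858283-170862828 held 25.4 ± 0.248, 15.03 ± 0.0678 and 23.1 ± 0.560 on the same base.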

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

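The test below was chosen after the data had been seen. The main results use reads of other chromosomes in the share on chr5 and in the counts and overlap of calls, but do not compare how they spread over those chromosomes. In S1KO, the stretch chr11:1-10000000 had more fragments with reads than in EV, 47.3 ± 0.433 against 34.0 ± 3.74 of every 10000 covered fragments (SD, n = 2 each; log2 0.48, SE 0.11, edgeR adjusted p = 0.031), a signal above the control level in both S1KO libraries. DKO stood at 45.6 ± 2.92. With windows of 5 Mb the edgeR calls for S1KO were 2, both lower than EV. Without EV replicate 1, or without either S1KO library, no window was called higher in S1KO, so the call depends on each of these libraries. No explanation was tested.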

How the results depend on the processing

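The near-viewpoint windows, the ratio of reads above to below the viewpoint, the overlap on chr5 alone, the 20-read search and all their alternatives were chosen after the data had been seen.

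The named near windows kept their direction under each of the 4 other scalings, and the number past the threshold changed. In the DKO comparisons these windows had been picked among the largest changes, which a shift of all windows by scaling could hardly turn. Of 349 alternative values of named near windows, 228 kept direction and side of the threshold, 113 were weaker, 1 stronger and 7 reversed. DKO against EV gave 14 windows, and 5 with 25-kb windows, 26 with DESeq2, 0 with numbers of fragments with at least 1 read (1 at an unadjusted edgeR p under 0.05), 9 with reads capped at the 90th percentile, and 4 to 17 with 1 library left out. In a fit of only the 4 libraries compared with a replicate block, it gave 12 with the replicates as numbered and 9 with the numbers of 1 group crossed, and DKO against S1KO gave 10 and 0. DKO against S1KO gave 12, and under the same alternatives 0 (25-kb windows), 20 (DESeq2), 0 (numbers of fragments), 2 (capped) and 0 to 7 (1 library left out), while with TMM it gave 2, with DESeq2 size factors 5 and with chr5 totals 4. S1KO against EV gave 0 to 3 with 1 library left out and 0 by edgeR and DESeq2 otherwise.

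The reversals of near windows lay in 2 settings. With numbers of fragments with at least 1 read, the window starting at 150 kb stood at log2 -0.26 for S1KO against EV and -0.38 for DKO against EV, that at 100 kb at -0.20 for DKO against EV and -0.12 for DKO against S1KO, and that at -200 kb at -0.0742 for DKO against S1KO. With capped reads the window at 150 kb stood at -0.00867 for S1KO against EV and -0.10 for DKO against EV. Counting fragments gives every fragment the same weight, and most fragments 100 to 500 kb above the viewpoint had reads in each library (76 to 90 of 92), so this setting hardly shows a gain in reads there; for the capped reads the cause was not tested. The chr5 window at -46500 kb stood between -10.61 and 0 for S1KO against EV with 1 library left out, at 0 without EV replicate 1, the only one of those 4 libraries with reads there.

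The ratio of reads above to below from 250 kb to 11 Mb kept its sign for DKO. By numbers of fragments it was -0.58 against EV and -0.57 against S1KO, with capped reads -0.83 and -0.76, and with 1 library left out -1.08 to -1.004 and -1.06 to -0.89. For S1KO against EV it lay between -0.15 and 0.02 with 1 library left out. From 10 to 250 kb, DKO minus EV was 0.54 by reads and -0.30 by numbers of fragments, which rests on EV replicate 2: the libraries stood at -0.24 and 0.24 in EV and at -0.29 and -0.31 in DKO.

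Across chr5, 302 of 355 alternative values of named fragments and windows kept direction and side of the threshold, 42 were stronger, 10 weaker and 1 reversed. Fragment calls for S1KO against EV, DKO against EV and DKO against S1KO were 0, 0 and 0 by edgeR, and 21, 28 and 22 by DESeq2. Without a filter DKO had 2 against EV and 2 against S1KO, with a replicate block 12 and 7, and with 1 library left out 0 to 0 and 0 to 1. Window calls by DESeq2 were 25, 87 and 54, with 28 of the 87 higher and 59 lower. For DKO against EV the 2 windows became 10 with DESeq2 size factors, 5 without TMM, 6 with 20-kb windows, 0 with 200-kb windows, 0 with only the 4 libraries compared, 0 with reads capped at the 99th percentile and 0 to 14 with 1 library left out. DKO against S1KO had 4 with DESeq2 size factors and 2 without TMM. These causes were not tested.

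Calls by the authors depended on the rule. Called in at least 1 replicate, S1KO kept 12, lost 150 and gained 73, and DKO kept 12, lost 150 and gained 11. At q below 0.01 DKO gained 0, and at q below 0.1 each knockout lost 1. Counting a call within 10 kb as the same, S1KO gained 2 and DKO 0. With 1 library left out, S1KO kept 7 to 10, lost 0 to 99 and gained 4 to 47, and DKO kept 6 to 9, lost 0 to 99 and gained 1 to 9. By numbers of fragments, DKO minus EV was 5.32 points for the share on chr5 and 0.215 for that within 1 Mb. With 1 library left out these lay between 9.22 and 20.8 and between 11.2 and 22.7, and for S1KO minus EV between -0.790 and 9.69 and between 0.732 and 12.3. With 20 reads as the minimum, 3 fragments had EV reads and none in S1KO, and 2 none in DKO. On chr5 alone the overlap within groups exceeded that between groups by 0.0666.

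With a library left out, 1 group holds a single library, assumed to vary like the others. The set tests of the 3 gene lists and their alternatives were not run, because gene positions on hg19 were not used here. Across chr5 the spread between libraries limits what can be called. With the common dispersion of the real fit given to every feature, simulated 16-fold changes at this depth were recovered in 0% of fragments and 0% of windows. With a dispersion of 0.1 they were recovered in 62% and 92%. The real fit called windows with many reads at log2 2.08 and 2.05, so the 0% does not hold for those.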

Other observations

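The measures weighed in this part were chosen after the data had been seen, and the tests of the absolute ratio at 250 kb to 2 Mb, of the difference at 2 to 11 Mb and of the 5-Mb windows of chr18 were chosen after the result was seen.

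Beyond chr5, the knockout cells differed from EV in a few stretches of other chromosomes. On chr18, the window chr18:20000001-30000000 held 52.1 ± 2.47 of every 10000 covered fragments in EV, 34.9 ± 1.45 in S1KO and 30.8 ± 0.961 in DKO (SD, n = 2 each), and chr18:30000001-40000000 held 42.9 ± 0.447, 28.1 ± 5.45 and 23.4 ± 2.02. For DKO against EV these were log2 -0.76 (SE 0.10, edgeR adjusted p = 0.0019) and -0.88 (SE 0.14, edgeR adjusted p = 0.0044). For S1KO against EV they were -0.58 (edgeR adjusted p = 0.013) and -0.62 (edgeR adjusted p = 0.029). DKO was lower than EV also at chr1:20000001-30000000 (log2 -0.59), chr8:30000001-40000000 (log2 -0.68) and chr12:40000001-50000000 (log2 -0.46), 5 windows of 281 in all, with 0 higher. S1KO was lower than EV in 9 windows and higher in 1, among them chr4:60000001-70000000 (log2 -0.54) and chr4:80000001-90000000 (log2 -0.41), where DKO held 30.1 ± 1.55 and 41.6 ± 1.33 against 32.5 ± 1.87 and 44.4 ± 0.646 in EV. Both comparisons use the same EV libraries, so part of what they share may come from those, and with the replicate number as a block S1KO had 0 calls and DKO 3. S1KO had 3 calls without EV replicate 1, 5 without EV replicate 2, 0 without S1KO replicate 1 and 2 without S1KO replicate 2. DKO had 4 without EV replicate 1, 1 without EV replicate 2 and 3 without either DKO library.

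A first pattern is the lower ratio of reads above to below the viewpoint in DKO. More background ligation in EV would bring its ratio nearer to 1. At 250 kb to 2 Mb it was DKO that lay nearer to 1 (absolute log2 ratio, DKO minus EV, -1.34, SE 0.086). All libraries had ratios above 1 there, so this is the value of the pattern itself and no separate test. The read density of other chromosomes was also subtracted. DKO minus EV was then -1.41 (SE 0.078) at 250 kb to 2 Mb and -0.95 (SE 0.33) at 2 to 11 Mb, so background of that density leaves the difference in place. At 2 to 11 Mb this is less certain. The amount subtracted there was 21.1% and 60.3% of the reads above in the EV libraries and 36.2% and 15.8% in DKO. The DKO libraries then stood at -1.77 and -1.13. A few heavily amplified fragments are argued against as the whole cause, since with reads capped at the 90th percentile the difference from 250 kb to 11 Mb was still -0.83 (SE 0.096). A loss or displacement of the telomeric end of chr5 on part of the copies in the DKO cells stays open, since the difference of -0.87 (SE 0.17) at 2 to 11 Mb is part of the pattern itself and decides nothing. A contact change caused by removing the silencers also stays open and was not tested apart from the clone or pool that carries it.

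If chr5 were joined to another chromosome just above FGF18 in DKO, that partner should have gained reads. Over 1369 windows of 2 Mb on other chromosomes, the highest value reached in both DKO libraries was 9.07 reads per 1000 near reads. That is 5.19% of the 175 per 1000 by which the DKO share from 250 kb to 2 Mb above was lower. The share rose by 86.5 at 100 to 200 kb above and by 74.3 at 100 kb to 2 Mb below. The 175 is thus a difference in shares and shows no loss for a partner to take over, so this comparison cannot decide on a junction. It shows only that no such window exceeded 9.07 in both DKO libraries. The 9.07 is a level and not a gain over EV. Both DKO libraries exceeded both EV libraries in 1 of the 1369 windows, where the lower DKO value was 0.154. DKO held a smaller share of its reads on other chromosomes, which by itself lowers such values in DKO.

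A second pattern is the set of stretches on other chromosomes lower in DKO than in EV. Counting noise of single windows would leave neighbours unrelated, but the log2 ratios of 257 pairs of neighbouring 10-Mb windows correlated at 0.36 (permutation p = 1e-05, the smallest that 100000 resamples can give). These pairs cover all windows and not only the called ones, and no comparison within a group was made. The correlation therefore shows only that the ratios as a whole are not counting noise alone. It does not tell differences between groups from differences between libraries. On chr18 the 5-Mb windows from 20 to 40 Mb lay between -0.94 and -0.71 for DKO against EV, and between -0.69 and -0.49 for S1KO against EV. The nearest ones on either side lay at -0.09 (SE 0.28) and -0.08 (SE 0.22) for DKO, and at -0.06 (SE 0.27) and 0.20 (SE 0.20) for S1KO. The flank at 15 to 20 Mb is imprecise, but a step showed at the 40-Mb edge. For DKO the ratio went from -0.94 (SE 0.21) at 35 to 40 Mb to -0.08 (SE 0.22) at 40 to 45 Mb. For S1KO, against the same EV libraries, it went from -0.59 (SE 0.19) to 0.20 (SE 0.20). All chr18 windows outside 20 to 40 Mb lay between -0.30 and 0.21 for DKO and between -0.18 and 0.45 for S1KO. Such a step cannot tell fewer copies from fewer contacts, so whether DKO has fewer DNA copies of this stretch than EV stays open. Base composition could not be tested without a genome of this build, and a difference in how these regions meet FGF18 also stays open.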
